A study of Populus x canadensis with 12 samples.

How the data were processed

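Leaf RNA of 12 single poplar plants was sequenced. The plants were rooted cuttings of 2 hybrids, 85 and 89, from a cross of Populus deltoides with Populus nigra (the hybrid species Populus x canadensis), grown in a greenhouse. Per the labels, each hybrid gave 2 plants in each of 3 stages: watered controls (C), moderate drought (D1) and severe drought (D2). The labels give 8 and 13 days without water but do not tie the days to the stages; the shorter period is taken here as D1 and the longer as D2. Clone numbers in the labels differ for all 12 libraries, so replicates are separate plants. Total RNA was made into libraries with a TruSeq kit and sequenced on an Illumina HiSeq2000, per the labels.

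The deposited values are RPKM (reads per kilobase of gene model and per 1e+06 reads), computed by the authors for each library, per the file header. Trimmomatic 0.32 is named in the submitters' processing notes. The aligner, the counting tool, its use of strand and of reads that map to several places, the genome build and the annotation version are not given in the sources used here. Reads shared between near-identical gene copies, overlapping genes or antisense partners are therefore uncertain for every gene. The 3 further columns with the authors' stage means were not used. The table has 41335 gene IDs and does not pair them with gene names, and no annotation was used here. IDs are printed as deposited, the chromosome is the number written in the ID, and no coordinates or gene functions are given. The gene lists and cell type markers fixed before the data were examined could not be matched to IDs, so the planned gene list tests were not run.

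The depth was read from the values. Each value is a whole number of reads times what 1 read is worth for that gene and library, so library totals, coding lengths and reads could be recovered. With a tolerance of 0.01 reads, 100.0% of the values above 0 came out whole, and the recovered reads summed to at least 99.99% of each recovered total. Recovered lengths were multiples of 3 bp in 100.0% of 1902 well-read genes when no such step was imposed, so they are coding lengths; the median was 1107 bp over the genes tested. In genes with few reads the recovered length is the smallest that fits. On simulated RPKM values of 4000 genes, all 12 totals and 100.0% of the reads were recovered. Totals ranged from 2259634 to 10509089 reads, a ratio of 4.65. The median tested gene had 19 reads in the shallowest library and 99 in the deepest. At the median coding length, 3 reads correspond to 0.258 RPKM in the deepest library and 1.199 RPKM in the shallowest. Such floors cover counting error only.

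Because the unit is RPKM, log2(RPKM + 1) was tested with limma 3.58.1 in R 4.3.3. Fold changes are on this scale, which understates the change of low genes. The 24117 genes with at least 1 RPKM in at least 4 libraries were kept. Stage and hybrid entered as additive terms over all 12 libraries, with the trended empirical Bayes variance and Benjamini-Hochberg adjusted p below 0.05. Differences between hybrids in the drought effect were tested in a model with 6 groups of 2 libraries. On simulated counts for the comparison of D2 with C (5 draws, about 24531 genes tested, 200 genes changed, dispersion 0.08), limma recovered 86.8% of genes changed 4-fold and 11.2% of genes changed 2-fold, with 7.2 false calls on average. An unchanged comparison gave 0 calls. In the measured data 40.8% of genes were called in D2 against C, a far larger part than was changed in the simulation. The adjusted threshold is then looser, so these recovery rates do not carry over to that comparison. To look for a library deposited more than once, replicates were compared by a chi-square of their recovered reads. The statistic per degree of freedom was 5.86 to 39.3, so no pair looked like a repeat of 1 library; separate plants differ by more than sampling noise, and this says nothing else of the replicates.

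For each stage and hybrid comparison the rule for named genes took, by ID, the 2 largest rises and the 2 largest falls. Eligible genes had adjusted p below 0.05, a mean of at least 5 RPKM over 12 libraries and complete separation of the groups. For differences between hybrids in the drought effect it took the 3 smallest p-values. These rules, the tests and most alternatives were fixed before the data were examined. The alternatives were other pseudocounts, filters, scalings and variance models, other covariates, a replicate block, a fold threshold, and each library left out in turn. Limma-voom on the recovered reads, reads thinned to the shallowest library, and the classes of genes by level, coding length and chromosome number were chosen after seeing the data. Level classes use the mean RPKM over all 12 libraries, and, for D2 against C, also the mean of the C and D2 means weighted alike, a cut added after seeing the data. Class tests used limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and reads were recovered with numpy 2.4.6 and pandas 2.3.3.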

Results

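Leaf transcript levels were measured in 12 poplar plants, 4 in each of 3 watering stages. The stages were watered control (C), moderate drought (D1) and severe drought (D2), and each held 2 plants of hybrid 85 and 2 of hybrid 89. Between 20689 and 22949 genes reached 1 RPKM in a library. Library totals were 2534325 to 10509089 reads in C, 3181833 to 4847233 in D1 and 2259634 to 3931067 in D2. The comparisons below ask how leaf transcripts differed between stages of water deprivation, and between the hybrids. The same control plants served for both drought stages, and harvest day and plant age are not among the sample labels used here. Effects of time therefore cannot be told apart from those of drought.

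On average, libraries of one stage resembled each other more than those of other stages, although single libraries overlapped: replicate 1 of hybrid 89 in D1 had a mean correlation of 0.891 with D1 and 0.891 with C. The mean Pearson correlation across genes of log2(RPKM + 1) was 0.93 within C, 0.90 within D1 and 0.897 within D2. It was 0.871 between C and D1, 0.757 between D1 and D2, and 0.696 between C and D2. The first principal component held 52.8% of the variance and ordered the stages without overlap: C lay between -98.2 and -77.3, D1 between -63.9 and -24.9, and D2 between 99 and 189.9. The second component, with 12.9%, placed both D1 libraries of hybrid 85 at 80.5 and 91.4, apart from D1 of hybrid 89 at -24.6 and -0.2. Replicate 1 of hybrid 89 in D2 was the most extreme library on the first component, and its mean correlation with the other D2 libraries was 0.862 against 0.903 to 0.915 for those.

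**Figure D1:**
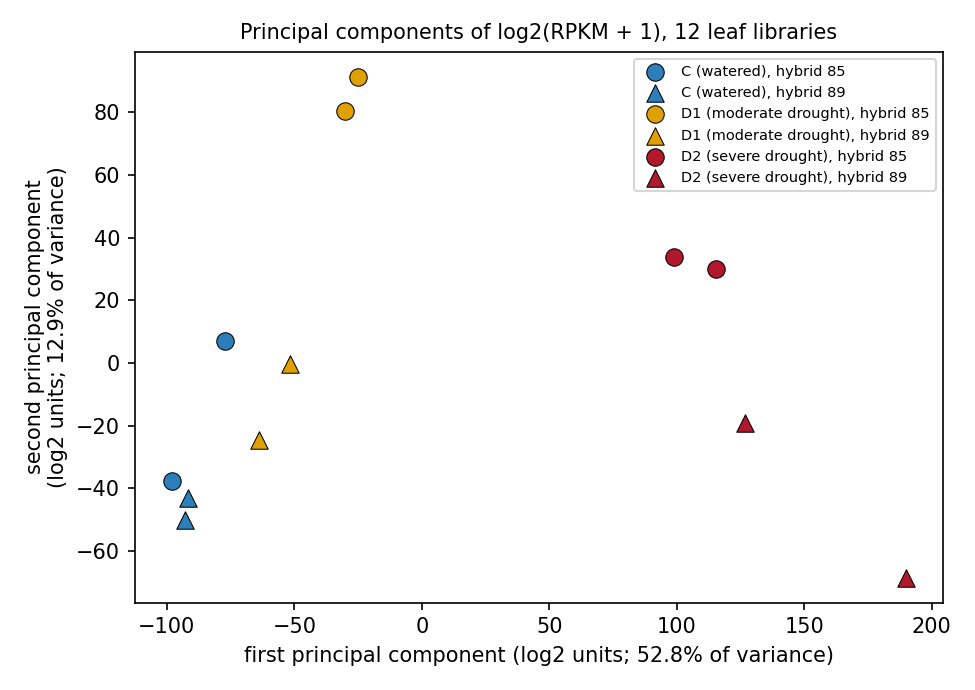
Scores of the 12 libraries on the first 2 principal components of log2(RPKM + 1), in log2 units; colour marks the stage, circles hybrid 85 and triangles hybrid 89. The 4 D2 libraries lie between 99 and 189.9 on the first component, above all C and D1 libraries.

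A large part of the leaf transcriptome differed between severe drought and control. Of 24117 genes tested, 5219 were higher and 4627 lower in D2 than in C (limma, adjusted p below 0.05), which is 40.8% of the genes. The median size of the called changes was 1.53 on the log2 scale. On the log2(RPKM + 1) scale the largest rise among eligible genes belonged to Potri.013G101000.1 (chromosome number 13, coding length 990 bp), which went from 1.05 ± 0.54 RPKM in C to 3312 ± 952 RPKM in D2 (SD, n = 4), a ratio of means of 3170. Its log2 change was 10.65 ± 0.37 (SE, limma adjusted p = 2.68e-09). Potri.008G149200.1 (chromosome number 8, 903 bp) rose from 2.00 ± 1.19 to 4877 ± 5056 RPKM, a log2 change of 9.95 ± 0.58 (limma adjusted p = 9.67e-08), and its D2 values spread from 488.4 to 11810 RPKM. The largest falls were in Potri.018G025900.1 (chromosome number 18, 366 bp) and Potri.013G141900.1 (chromosome number 13, 633 bp). The former went from 4119 ± 3283 to 4.66 ± 1.29 RPKM, a log2 change of -9.20 ± 0.79 (limma adjusted p = 2.67e-06). The latter went from 1853 ± 972 to 2.21 ± 1.07 RPKM, a log2 change of -9.08 ± 0.49 (limma adjusted p = 6.86e-08). Each of these 4 genes moved in its direction in all 4 D2 libraries, as the rule for named genes required. In 8868 genes, 36.8% of those tested, the D2 and C values did not overlap, where chance gives 2.86%.

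**Figure D2:**
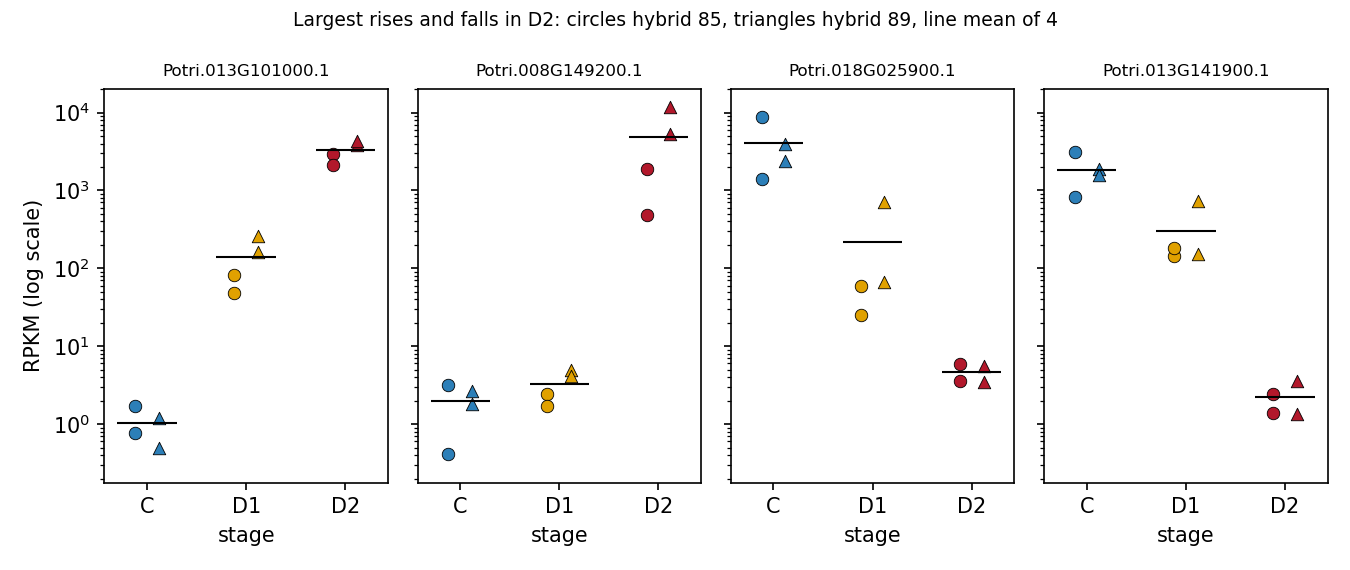
RPKM on a log axis in each library for the genes with the 2 largest rises and the 2 largest falls in D2 against C; circles are hybrid 85, triangles hybrid 89, and the line is the mean of the 4 libraries of a stage. Potri.013G101000.1 has a mean of 1.05 RPKM in C, 138.3 in D1 and 3312 in D2, while Potri.018G025900.1 has 4119, 217.3 and 4.66 RPKM.

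The genes with the most abundant transcripts fell most often in D2. Among 233 genes with a mean of 500 RPKM or more over the 12 libraries, 118 fell, 52 rose and 63 were not called, and the class median log2 change was -1.14. This cut holds 8 libraries of C and D1 and 4 of D2, so it favours genes that fell. With the means of C and D2 weighted alike, 115 of 241 genes fell and 65 rose, with a median of -0.84. For the fall of this evenly weighted class against other genes, camera gave adjusted p = 0.0121 with a preset correlation, and adjusted p = 0.553 with an estimated correlation. By the mean over 12 libraries, genes of 50 to 500 RPKM went the other way: of 3092, 1266 rose and 746 fell. Their median was 0.38, which was 0.06 with quantile normalization and 0.23 with median-ratio scaling. With even weights, 1384 of 3144 rose and 712 fell. The median was 0.47, or 0.15 with quantile normalization and 0.32 with median-ratio scaling. For this evenly weighted class camera gave adjusted p = 0.00106 and 0.347 with the preset and the estimated correlation. RPKM is relative to all reads of a library. The evenly weighted genes of 500 RPKM or more took 34.7% of the reads in C and 23.2% in D2. A smaller part of the reads in these genes raises the RPKM of the others. Part of the rise of genes of 50 to 500 RPKM may be of this kind, and how much was not tested. By the 12-library mean, among 8471 genes under 5 RPKM, 857 rose and 1518 fell. Their median was -0.14, and it was 0.06 with quantile normalization and -0.22 with median-ratio scaling. The 100 most read genes of each library, which need no such cut, took 29 ± 2.88% of all reads in C, 27.2 ± 1.45% in D1 and 21.4 ± 1.72% in D2 (SD, n = 4). The decrease from C to D2 had p = 0.0286 in a two-sided exact permutation test, the smallest p that 4 against 4 libraries can give (adjusted p = 0.0429 over 6 exact tests). Some of the relabelings in this test do not hold the hybrids evenly in both groups, as the real stages do. Among those that do, the smallest possible p is above 0.05, so this test alone cannot exclude chance. No difference between D1 and C was detected in the read share of the 100 most read genes (exact permutation p = 0.314, adjusted p = 0.343). Without replicate 1 of hybrid 89 in D2, the median of the genes of 500 RPKM or more was -0.69 by the 12-library mean and -0.45 with even weights, and 118 and 115 genes were lower in that fit.

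**Figure D3:**
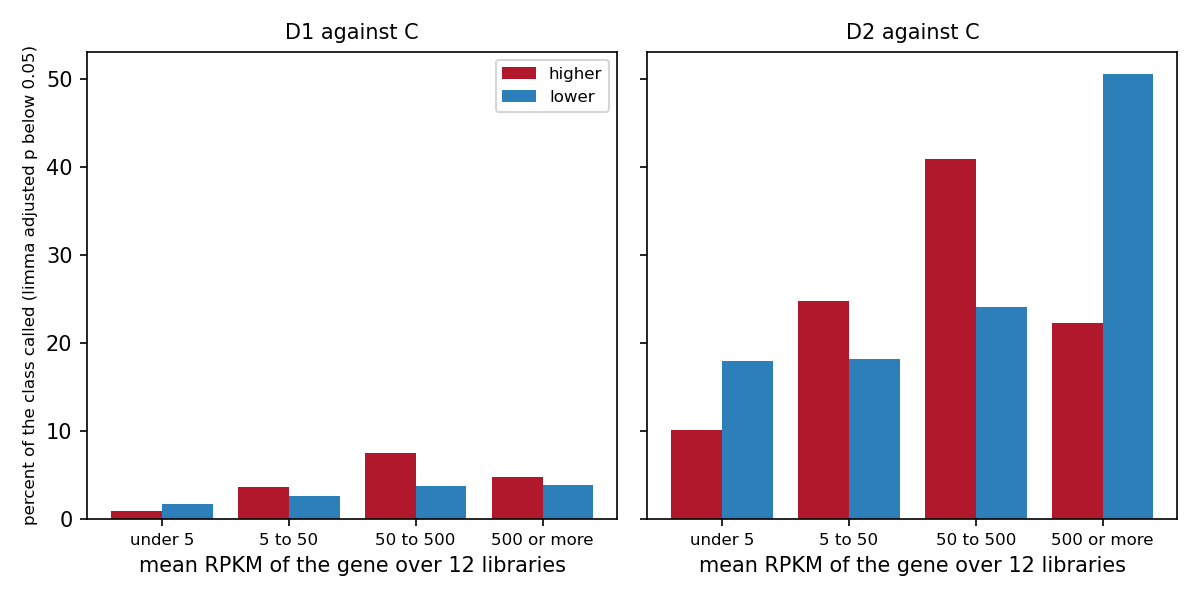
Percent of the genes in each class of mean RPKM over 12 libraries that were higher or lower (limma adjusted p below 0.05) in D1 or D2 than in C. In D2, 50.6% of the genes of 500 RPKM or more were lower and 22.3% higher.

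Some genes were read in 1 stage and hardly at all in another. In D2 against C, 69 genes had at least 10 reads in each D2 library and at most 3 reads over all 4 C libraries. The reverse held for 217 genes. The C libraries held more reads than the D2 libraries. With every library thinned to the depth of the shallowest, the counts were 128 and 178. By coding length, 23.9% of the 6072 shortest genes (96 to 657 bp) rose in D2 and 15.4% fell, while 17.1% of the 6016 longest (1677 to 16233 bp) rose and 19% fell.

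Fewer genes differed between moderate drought and control. In D1, 758 genes were higher and 584 lower than in C (limma, adjusted p below 0.05), or 5.56% of those tested. On the log2(RPKM + 1) scale the 2 largest rises were in Potri.013G101000.1 and Potri.004G044300.1. Potri.013G101000.1 went from 1.05 ± 0.54 to 138.3 ± 93.7 RPKM (SD, n = 4), a log2 change of 5.86 ± 0.37 (SE, limma adjusted p = 1.82e-05). Potri.004G044300.1 (chromosome number 4, 1023 bp) had 2 reads in all C libraries together and 73.8 ± 59.3 RPKM in D1, a log2 change of 5.70 ± 0.47 (limma adjusted p = 6.49e-05). Their order turned with a pseudocount of 0.1, at 6.77 and 8.67, with 0.5, at 6.28 and 6.63, and with limma-voom on the recovered reads, at 6.72 and 8.42. The largest falls were in Potri.014G149700.1 (chromosome number 14, 1743 bp), from 889.4 ± 860.5 to 7.06 ± 1.96 RPKM, and Potri.004G155400.1 (chromosome number 4, 300 bp), from 622.9 ± 529.4 to 4.53 ± 2.28 RPKM. Their log2 changes were -6.41 ± 0.43 and -6.33 ± 0.65 (limma adjusted p = 1.82e-05 and 0.000195). D1 and C values did not overlap in 3595 genes, 14.9% of those tested against 2.86% by chance.

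The balance of rises and falls against C depended on the scaling. The median log2 change of all genes was 0.14 in D1 and 0.07 in D2 against C, and -0.13 in D2 against D1, and changes are to be read relative to these shifts. The share of D1 calls that were rises was 56.5%, and it was 42.8% with quantile normalization (715 higher, 955 lower) and 35.4% with median-ratio scaling (524 higher, 958 lower). For D2 the share was 53%, and it was 49.7% with quantile normalization (4672 higher, 4735 lower) and 45.3% with median-ratio scaling (4446 higher, 5374 lower). The D1 count was 2099 without replicate 1 of hybrid 89 in D2, a library that enters it only through the shared variance and the hybrid term. It was 743 without replicate 2 of hybrid 85 in C, 705 and 772 without replicates 1 and 2 of hybrid 89 in C, 718 and 712 without replicates 1 and 2 of hybrid 85 in D1, and 702 without replicate 2 of hybrid 89 in D1.

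From D1 to D2, 3821 genes rose and 4390 fell (limma, adjusted p below 0.05). The largest rises were in Potri.012G033900.1 (chromosome number 12, 906 bp), from 1.23 ± 0.95 to 2021 ± 1649 RPKM (SD, n = 4), and in Potri.008G149200.1, from 3.31 ± 1.48 to 4877 ± 5056 RPKM. Their log2 changes were 9.64 ± 0.34 and 9.39 ± 0.58 (SE, limma adjusted p = 6.51e-09 and 3.03e-07). Potri.001G348900.1 (chromosome number 1, 1038 bp) was among the most abundant transcripts in C, at 9177 ± 2997 RPKM. It stood at 7572 ± 1240 RPKM in D1 and fell to 58.6 ± 22.1 RPKM in D2, a log2 change of -7.06 ± 0.38 from D1 (limma adjusted p = 1.66e-07). Potri.019G093400.1 (chromosome number 19, 1839 bp) fell from 296.7 ± 203.6 to 1.61 ± 2.05 RPKM, a log2 change of -6.97 ± 0.45 (limma adjusted p = 4.66e-07).

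**Figure D4:**
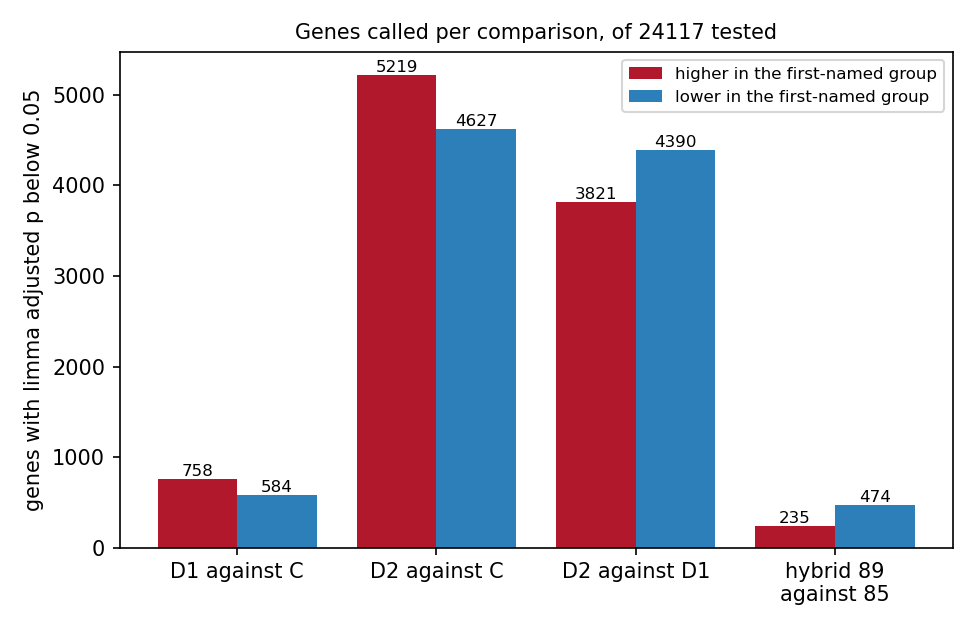
Number of genes with limma adjusted p below 0.05 in each comparison, of 24117 tested; red bars count genes higher and blue bars genes lower in the first-named group. D2 against C has 5219 higher and 4627 lower genes, and D1 against C has 758 and 584.

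Most genes called in D1 were called in the same direction in D2. Of the 758 genes higher in D1, 532 were higher in D2, 13 lower and 213 not called. Of the 584 lower in D1, 454 were lower in D2, 36 higher and 94 not called. Independent lists of these sizes would share 164 higher and 112 lower genes. Groups simulated without any effect against the same controls shared 0 higher and 0.02 lower genes on average over 50 simulations; such groups yield almost no calls, so this does not measure the part of the overlap that the shared controls add. With 2 of the controls used for D1 and the other two for D2, 111 to 314 genes were higher in both, against 20.79 to 79.49 for independent lists, and 82 to 241 were lower in both, against 13.29 to 47.65. The log2 changes of D1 and D2 correlated across genes at r = 0.55, and 66.4% of genes had the same sign. Noise simulated with shared controls gave 0.50 and 66.6%. Such noise gives these values at any level of spread, so they do not measure the controls' part of the observed ones. The covariance of the log2 changes was 0.578 against 0.0721 simulated. With the controls split, so that no library was shared, r was 0.437 to 0.509. The share with the same sign was then 61.2 to 64.3%, and the covariance 0.507 to 0.525. Across hybrids, which also share no libraries, D1 in hybrid 85 and D2 in hybrid 89 correlated at r = 0.427 (same sign 60.1%). For D1 in hybrid 89 and D2 in hybrid 85, r was 0.28 (same sign 52.1%). Among D1 rises, 180 genes rose further from D1 to D2 and 176 fell back, the latter with a median log2 change against C of 1.57 in D1 and 0.18 in D2. Among D1 falls, 196 fell further and 115 rose again. Both comparisons use the same D1 libraries, so D1 values that were extreme by chance add to these returns. That part was not measured.

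The hybrids differed in 709 genes, against 1342 between D1 and C, and the order turned without replicate 2 of hybrid 85 in C, at 761 and 743. With stage in the model, 235 genes were higher and 474 lower in hybrid 89 than in hybrid 85 (limma, adjusted p below 0.05), 2.94% of those tested. Potri.016G092500.1 (chromosome number 16, 315 bp) had 72.6 ± 32.6 RPKM in hybrid 89 and 0.27 ± 0.43 RPKM, from 3 reads in all, in hybrid 85 (SD, n = 6). Potri.010G155500.1 (chromosome number 10, 297 bp) had 34.8 ± 10.1 RPKM in hybrid 89 and 1 read in all 6 libraries of hybrid 85. Their log2 differences were 5.79 ± 0.32 and 5.05 ± 0.22 (SE, limma adjusted p = 2.08e-06 and 2.06e-07). In the other direction, Potri.T100200.1 (no chromosome number in its ID, 213 bp) had 105.9 ± 104.4 RPKM in hybrid 85 and 0.93 ± 1.94 in hybrid 89. Potri.015G112300.1 (chromosome number 15, 795 bp) had 80.95 ± 46.9 RPKM in hybrid 85 and 1.43 ± 0.50 in hybrid 89. Their log2 differences were -5.59 ± 0.48 and -4.88 ± 0.33 (limma adjusted p = 5.83e-05 and 1.3e-05). Values of the hybrids did not overlap in 321 genes, 1.33% of those tested against 0.216% by chance. Gene copies that are present or alike in only 1 hybrid may also give such differences in reads. Sequences to tell this from a difference in transcript level were not used here. The count fell most when 1 of the D1 plants was left out, as given below. A comparison of the hybrids within D1 alone called 689 genes. How many of these are among the 709 is not given here, so the part of the list that rests on D1 stays open. A difference held alike in all stages is not shown for the list as a whole. The count of 709 fell to 448 without replicate 1 of hybrid 89 in C, 350 and 372 without replicates 1 and 2 of hybrid 85 in D1, 339 and 338 without replicates 1 and 2 of hybrid 89 in D1, and 469 without replicate 2 of hybrid 85 in D2.

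Genes that differed between the hybrids were unevenly spread over the chromosome numbers. They made up 5.02% of the tested genes of chromosome number 17 (43 of 856) and 5.56% of those of 19 (37 of 665), but 1.04% of those of 9 (11 of 1060). The adjusted p over 20 Fisher's exact tests was 0.00313, 0.00166 and 0.000358. Genes without a chromosome number in the ID reached 8.56% (62 of 724, adjusted p = 1.04e-12 by the same exact test). These p-values treat genes as independent, which neighbouring genes are not. In D2 against C the range over chromosome numbers was 37.2% to 45%.

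**Figure D5:**
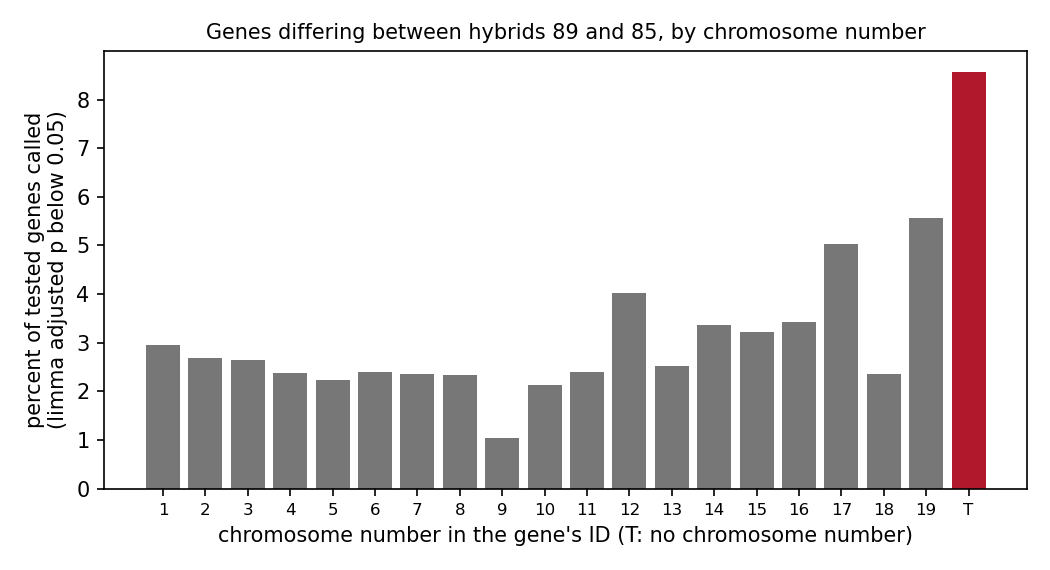
Percent of tested genes that differed between hybrids 89 and 85 (limma adjusted p below 0.05) for each chromosome number in the gene ID; T stands for IDs with no chromosome number. T reaches 8.56%, chromosome number 19 reaches 5.56% and chromosome number 9 has 1.04%.

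The drought effect was also taken within each hybrid. In D2 against C, 3253 genes rose and 3358 fell in hybrid 85, and 5595 rose and 4094 fell in hybrid 89 (limma, adjusted p below 0.05, 2 libraries per group). The median D2 change of all genes was -0.06 in hybrid 85 and 0.18 in hybrid 89. The values of hybrid 89 include its replicate 1 in D2, the most extreme library. The D2 effects of the hybrids, which share no libraries, correlated across genes at r = 0.785, and the D1 effects at r = 0.392. In D1, 653 genes rose and 820 fell in hybrid 85, and 1029 rose and 306 fell in hybrid 89. The median D1 change of all genes was -0.01 in hybrid 85 and 0.26 in hybrid 89, with a median difference of 0.30, so part of this contrast in balance goes with a shift of all genes. A test of the difference itself called 0 genes for D1 by limma and by limma-voom on the recovered reads, with 4042 genes at unadjusted p below 0.05. From the limma p-values, the share of unchanged genes was estimated at 76.2%. With 2 libraries per group, 0 calls therefore do not show that the hybrids responded alike. The same test called 297 genes with library quality weights, 33 with equal RPKM sums and 32 with quantile normalization. The 3 smallest p-values for D1 belonged to Potri.012G141800.1, Potri.016G135200.1 and Potri.005G107700.1 (limma adjusted p = 0.0581 for each). Potri.005G107700.1 had 76.5 RPKM in D1 and 10.8 in C in hybrid 85, and 6.40 and 12.6 in hybrid 89. The count of 0 became 133 without replicate 1 of hybrid 85 in C, 2 without replicate 1 of hybrid 85 in D1, and 3 without replicate 2 of hybrid 89 in D1. Without replicate 1 of hybrid 89 in D2, 91 genes were higher and 32 lower, and without replicate 2 the count was 120.

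For D2 the effect differed between the hybrids in 113 genes, 82 with a higher and 31 with a lower log2 change in hybrid 89 (limma, adjusted p below 0.05). Potri.015G074500.1 (chromosome number 15, 537 bp) went from 5.73 to 127.1 RPKM in hybrid 89 and from 12.1 to 8.03 in hybrid 85. Potri.003G134500.1 (chromosome number 3, 1170 bp) went from 8.81 to 0.11 RPKM in hybrid 89 and from 3.73 to 12.9 in hybrid 85. Potri.T171300.1 (no chromosome number, 1323 bp) had 36.3 RPKM in C of hybrid 89 and 1 read in its D2 libraries, while hybrid 85 had 0 reads in both stages. Its difference in effect thus restates the fall in hybrid 89, and its size follows the pseudocount: it was -5.06 ± 0.50 in the main fit, and -7.70 ± 1.23 (SE) with a pseudocount of 0.1, where the larger SE ended the call (limma adjusted p = 0.0553). It was -8.38 with limma-voom (adjusted p = 0.0344). In the main fit the limma adjusted p was 0.00886 for each of these 3 genes. The log2 difference of Potri.015G074500.1 was 4.75, and 4.56 and 4.94 without replicates 1 and 2 of hybrid 89 in C. For Potri.003G134500.1 it was -4.75, and -4.69 and -4.80 without them. The median difference of all genes was 0.21, and with median-ratio scaling 24 genes were higher and 37 lower. This count depended on single libraries: it was 31 without replicate 1 and 2596 without replicate 2 of hybrid 89 in D2, 0 without replicate 1 of hybrid 89 in C, and 0 without replicate 2. It was 27 without replicate 2 of hybrid 85 in C, 24 without replicate 1 and 24 without replicate 2 of hybrid 85 in D1, 41 and 43 without replicates 1 and 2 of hybrid 89 in D1, and 24 and 11 without replicates 1 and 2 of hybrid 85 in D2.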

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

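The tests of why 1 library lies apart were chosen after its position was seen, except the thinning bound, which was set before its value was known. Among 75 groups of 4 libraries examined, 10 had 1 library far from the other 3, where chance gives about 3.8. In 3 of the 10, 1 or 2 reads stood against 0 in the other libraries, where any read is flagged, and groups that share libraries are not independent, so the excess is not read as a pattern.

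The difference between hybrids in the D2 effect held for 113 genes by limma. It was flagged because the drought effect itself was tested between the groups, as were its named genes, with log2 differences of 4.75 in Potri.015G074500.1, -5.06 in Potri.T171300.1 (0 reads in C and D2 of hybrid 85, so this restates the fall in hybrid 89) and -4.75 in Potri.003G134500.1. Of the 113 genes, 60 had opposite signs in the hybrids and 98 had the larger change in hybrid 89. Genes picked for a difference in effect are bound to be rich in opposite signs, and over all genes 73% had the same sign. Changes were also larger in hybrid 89 among the 9846 genes called in D2, with a median size of 1.69 against 1.37 in hybrid 85. The values of hybrid 89 rest on 2 plants in D2 and include its replicate 1, the most extreme library. Neither the 98 genes nor these medians are given without it.

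Replicate 1 of hybrid 89 in D2 lay apart from the other D2 libraries, and without it 31 genes differed between hybrids in the D2 effect, 26 of them among the 113. Its depth of 2348388 reads was argued against as the cause: with all libraries thinned to one depth, its mean distance (1 - r) to the other D2 libraries was 1.37 times the largest of the others. A loss of long transcripts was also argued against, since its difference from the other D2 library of hybrid 89 had a Spearman correlation of -0.055 with coding length across genes. A response that went further in this plant stays open as a hypothesis: the same difference correlated at r = 0.224 across genes with the D2 effect in hybrid 85, measured in other libraries. Genes are not independent replicates, and a single plant cannot be told from its handling.

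Other libraries far from the rest of their stage are given as values. Replicate 1 of hybrid 89 in D1 had 719 RPKM of Potri.018G025900.1 (others 24.9 to 65.9), 721 of Potri.013G141900.1 (others 143 to 183) and 601 of Potri.019G093400.1 (others 179 to 225). Replicate 1 of hybrid 89 in C had 2170 RPKM of Potri.014G149700.1 (others 348 to 611). Replicate 1 of hybrid 89 in D2 had 4490 RPKM of Potri.012G033900.1 (others 1110 to 1240) and 0.557 of Potri.016G135200.1 (others 0). Replicate 2 of hybrid 85 in D2 had 10.1 RPKM of Potri.004G044300.1 (others 34.2 to 38.7), and replicate 1 of hybrid 85 in C had 0.186 (others 0). Replicate 2 of hybrid 89 in D2 had 0.192 RPKM of Potri.T171300.1 (others 0). Replicate 2 of hybrid 85 in D1 had 35.2% of its reads in genes of 500 RPKM or more (others 31.2 to 31.8%).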

How the results depend on the processing

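Voom, thinned reads and all settings for the class of 500 RPKM or more were chosen after seeing the data. Counts for D2 against C and D2 against D1 stayed within 1.5 times in every setting, at 7718 to 9966 and 6373 to 8382 genes. With each library left out, counts ranged from 702 to 2099 for D1 against C, 8458 to 9717 for D2 against C, 6373 to 8382 for D2 against D1 and 338 to 761 between hybrids. They ranged from 0 to 133 and 0 to 2596 for the hybrid differences of the D1 and D2 effects, and from 104 to 118 for falls in the class of 500 RPKM or more. Where 1 library was then left in a group, it was assumed to vary like the others. Library quality weights gave 2663 genes for D1 against C, 1284 between hybrids, and 297 and 23 for the D1 and D2 hybrid differences. Between hybrids, a mean of at least 5 RPKM gave 373 (fewer genes tested) and leaving out stage gave 148. The D1 hybrid difference had 3 genes with no filter, 33 with equal RPKM sums, 32 with quantile normalization and 1 with thinned reads. The D2 hybrid difference had 37 and 43 genes with pseudocounts of 0.1 and 0.5, 224 with no filter, 219 with equal sums, 58 with quantile normalization, 61 with median-ratio scaling, 71 with voom and 28 with thinned reads. Genes called alike in D1 and D2 numbered 986, and 232, 555, 193 and 466 with the controls split (fewer samples). Otherwise the cause was not tested. Replicate numbers did not pair the plants: same-numbered libraries deviated from their group means with correlations of -0.036 to 0.082. The replicate block gave 954, 9136, 7394 and 560 genes for the stage and hybrid comparisons, 0 for the D1 and 60 for the D2 hybrid difference. Of 556 values of named genes under alternatives, 0 reversed, 530 kept their side of the threshold, 7 lost it and 19 gained it. The named genes were picked from the same data for large changes or small p-values, so reversals were unlikely from the start. Their stability says little about other genes. The planned gene list alternatives were not run. Depth limits low genes most: the median gene had 19 reads in the shallowest library.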

Other observations

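The tests on genes without a chromosome number and on neighbouring genes were chosen after the pattern was seen; the matched sets were bounded before their result was known.

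Other splits of the libraries were set against the main counts. For each pair of stages the 8 libraries were split into 4 and 4, with the other 4 libraries kept in the model as in the main fit. Of 35 splits only 1, the real one, reached the 1342 genes of D1 against C, the 9846 of D2 against C or the 8211 of D2 against D1, and the highest other splits gave 48, 0 and 1. The smallest share these splits can give is 1 of 35. Some of these splits do not hold the hybrids evenly on both sides, as the real split does. Among those that do, the smallest possible share is above 0.05, so these splits alone cannot exclude chance. Between hybrids, 1 of 100 splits of the 12 libraries, the real one, reached 709 genes. The highest other gave 689. That split set all C libraries and the D1 libraries of hybrid 85 against the rest, so with stage in the model it again compared the hybrids, within D1. It does not hold the stages evenly on both sides, as the real split does. Splits uneven over the stages are partly tied to stage in the model, so their counts are not on a like footing with the 709.

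Genes whose IDs carry T in place of a chromosome number differed between hybrids in 8.56% of cases against 2.77% of the others, with 21 higher and 41 lower in hybrid 89. Low level or short coding length was argued against, since the highest of 1000 sets of other genes matched on both reached 5.66%. With each library left out the percentages were 4.28 to 8.56 against 1.3 to 3.02. These genes responded to D2 in 32.3% of cases against 41.1% of the others. Gene copies that are present or alike in only 1 hybrid, or reads shared between near-identical copies, may both give this, and sequences to tell them apart were not used here.

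Neighbouring genes tended to change together. In ID order along the chromosome numbers, limma's statistic for D2 against C correlated at r = 0.119 between adjacent genes, above the highest of 1000 shuffles, 0.023 (permutation p = 0.001, the smallest these shuffles can give). The correlation was 0.06 at 2 genes apart, 0.03 at 5 and 0.009 at 10. D1 against C gave 0.102 between adjacent genes and the hybrid comparison 0.092. A response shared by neighbours, such as copies of one gene, is a candidate explanation, and reads shared between such copies stay open.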
